A study of Homo sapiens with 9 samples.

How the data were processed

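Gene expression was measured by RNA sequencing in 9 libraries of EPC2, which the labels describe as a line of normal squamous cells from the human esophagus. The labels put 3 libraries in each of 3 groups: untreated cells, cells that received an empty vector with a lipid reagent that carries DNA into cells, and cells that received a FOXF1 plasmid with the same reagent. The design text calls them biological triplicates, and p-values measure the spread between these libraries. Libraries were made with a stranded kit for polyadenylated RNA, per the labels' protocols.

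The deposited values are raw read counts per Ensembl gene, with 64253 genes and a column for each library, per the file headers. The submitters' processing notes name bcl2fastq, the aligner STAR 2.5.2b, the counter HTSeq and the human genome build GRCh38. The strand setting of the counting, the annotation release and any read trimming are not given in the sources used here. Reads from overlapping or antisense genes, and reads that match a gene and its near-identical copies, can therefore be assigned in ways that the counts do not show. This matters for mitochondrial genes, whose nuclear pseudogenes carry nearly the same sequence. The counts also do not separate FOXF1 reads of the plasmid from those of the chromosomal gene. Coordinates are those of GENCODE release 29 on GRCh38, which holds 56591 of the 64253 gene identifiers.

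Library totals ranged from 34390666 to 39973289 counts. A gene with no read in a library could have a true level of up to 0.075 to 0.087 CPM, read counts scaled by library total, taking 3 counts as the limit. Intervals and such limits cover counting error only, because reads are not independent molecules. Replicate pairs differed by far more than sampling noise, with a chi-square per degree of freedom from 9.17 to 25.28, so all 9 libraries were kept as separate samples.

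Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 16366 genes, of which 13248 are protein coding. Library sizes were scaled by TMM factors. A quasi-likelihood model with a mean for each group was fitted to all 9 libraries, and each gene was tested by the quasi-likelihood F test with Benjamini-Hochberg adjustment. A gene was called changed at an adjusted p below 0.05. Group levels are CPM on TMM-scaled library sizes, as mean ± SD with n = 3, unless stated otherwise. Fold changes carry an approximate standard error (SE) derived from the test. It is the absolute log2 fold change divided by the square root of the F statistic. The common biological coefficient of variation was 0.101. On simulated data for the comparison of the FOXF1 plasmid with the empty vector, the test recovered 42.9% of the genes changed 1.25-fold, 75.7% of those changed 1.5-fold and 100% of those changed 2-fold, with 13 false calls among 16257 genes. For the empty vector against untreated cells it recovered 31.4%, 68.6% and 95% with 10 false calls among 16248 genes, and for the FOXF1 plasmid against untreated cells 31.4%, 68.6% and 96.7% with 7 false calls among 16261 genes. The simulations drew genes independently and changed 70, 70 and 60 genes, all with a mean log2 CPM above 1. For the FOXF1 plasmid against the empty vector, the 13 false calls stood beside 30, 53 and 60 recovered genes. Fewer true changes make the adjusted threshold stricter. Recovery in the real comparison of the FOXF1 plasmid with the empty vector, with 9 calls, may therefore be lower.

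The comparisons, the 25 gene lists and the rule for naming genes were fixed before the data were examined. Of the lists, 22 had at least 5 tested members. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry, which tests whether the members move on balance in a single direction and does not set them against other genes. The named genes were the 10 largest rises and 10 largest falls among the called genes with a mean log2 CPM of at least 1 and no overlap between groups (5 and 5 for the FOXF1 plasmid against untreated cells), without clone-style names or pseudogenes. Where fewer than 10 genes passed, all that passed were named, together with the 5 highest and 5 lowest fold changes among the 50 smallest unadjusted p-values, as values only. Members of each list and a fixed set of squamous, columnar and Hedgehog-related genes were added. Other genes named are said to be chosen after their values were seen.

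The fold changes of the transfected groups share the untreated libraries, so their correlation and covariance were set beside 100 simulated sets of 3 unchanged groups. With 3 control libraries, the controls could not be split into parts of at least 2. Alternatives were DESeq2 1.42.0, limma-voom, RLE factors, library size without a composition factor, no filter on low counts, a filter of 1 CPM in at least 3 samples, a fit of only the compared groups, a replicate block, a fold threshold of 1.2 and leaving out each library. After the data were seen, further alternatives were added: leaving out mitochondrial genes and their pseudogenes before scaling, which removed 36 tested genes, and offsets for the trend of each library with GC content and transcript length. GC content and length came from the longest GENCODE transcript and were known for 16213 of the 16366 tested genes. Gene lists were not rerun with the GC and length offsets. Another 5 gene lists were also chosen after the leading genes had been seen.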

Results

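The transcriptome of EPC2 cells, a line described as normal squamous epithelium of the esophagus, was measured in 9 libraries. Untreated cells, cells transfected with an empty vector and cells transfected with a FOXF1 plasmid contributed 3 libraries each. FOXF1 encodes a forkhead transcription factor of the Hedgehog-responsive mesenchyme. Total counts were 39973289, 39902108 and 37115645 in the untreated libraries, 37937873, 39354531 and 39708872 with the empty vector, and 39100049, 34390666 and 36877641 with the FOXF1 plasmid. The smallest library thus allows a level of up to 0.087 CPM (read counts scaled by library total) for a gene without a read.

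FOXF1 (ENSG00000103241; chromosome 16, 86510527 to 86515418, plus strand, GRCh38) was read almost exclusively in the plasmid group. The plasmid libraries held 367, 184 and 141 reads, or 9.39, 5.35 and 3.82 CPM of the library total, with exact 95% intervals of 8.45 to 10.4, 4.61 to 6.18 and 3.22 to 4.51. The untreated libraries held 1, 0 and 0 reads and the empty vector libraries 0, 0 and 6. The pooled level was 122-fold that of the empty vector group (95% counting interval 55.9 to 334) and 734-fold that of the untreated group (131 to 29000, from 1 untreated read). These ratios rest on 6 and 1 reference reads. The levels are averages over all cells of a library. The counts do not show which share of cells took up the plasmid, so the level per expressing cell is unknown. On TMM-scaled library sizes FOXF1 averaged 6.099 ± 2.75 CPM in the plasmid group, below SOX9 at 14.55 ± 0.554 (SD, n = 3). Whether a higher FOXF1 level would change more genes was not tested. The fitted log2 fold change against the empty vector was 6.92 ± 0.51 (SE), with an adjusted p of 8.8e-10 (edgeR quasi-likelihood test). With a library left out it ran from 6.34 to 10.85, a range that the SE does not cover. FENDRR, the noncoding neighbour of FOXF1, had 0 or 1 read in each of the 9 libraries.

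**Figure D1:**
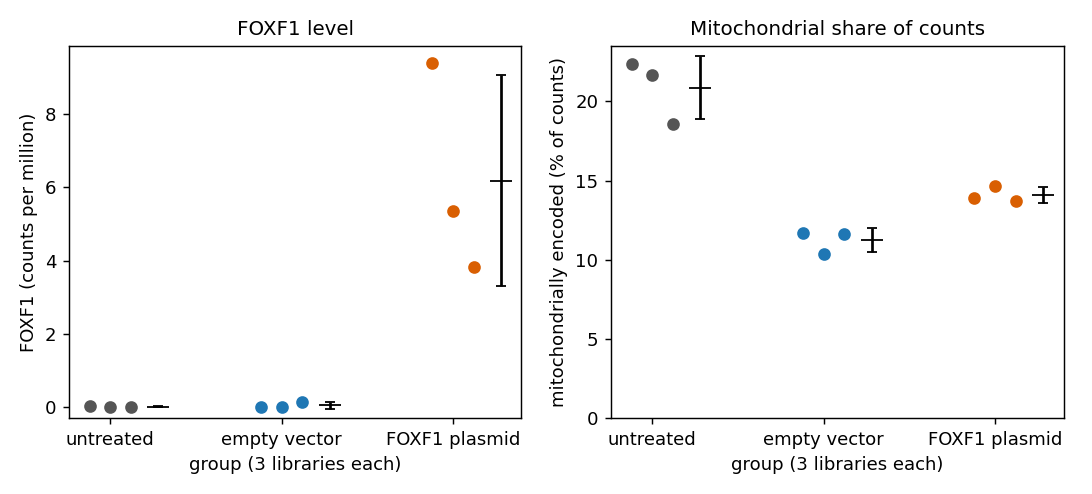
FOXF1 in CPM (left) and the mitochondrially encoded share of counts in percent (right) for each library, with the mean and SD of each group of 3. FOXF1 lies between 3.82 and 9.39 CPM in the plasmid libraries, and the mitochondrial share averages 20.9% in untreated, 11.2% in empty vector and 14.1% in FOXF1 plasmid libraries.

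Of 56 markers of squamous epithelium, 33 were at or near 0 in all 9 libraries, untreated ones included. The rest reached 1 CPM in at least 1 library, with means from 0.752 CPM (CSTA) to 114.3 CPM (PPL). TP63, the master regulator of squamous basal cells, had 0 reads among the counts of all 9 libraries pooled, which allows a level of up to 0.0087 CPM. Among squamous keratins, KRT5 (basal layer) had 8 to 19 reads per library and KRT13 (differentiating esophageal layer) 0 to 2, whereas KRT17 and KRT10 averaged 27.4 and 25.7 CPM. The 33 genes below 1 CPM in every library were 9 of the 20 basal and 24 of the 36 differentiation genes, and 15 had no read in any library. Expressed members included PPL and EVPL (cornified envelope; 114.3 and 92.1 CPM), ITGB4 (hemidesmosomes; 75.1 CPM), ECM1 (31.5 CPM), CDH3 (26.7 CPM) and PAX9 (an esophageal transcription factor; 16.9 CPM), singled out after their values were seen. The simple-epithelial keratins KRT7, KRT8 and KRT18 were abundant, at 1130 ± 51.8, 1396 ± 73.5 and 1277 ± 84.2 CPM of the library totals (SD, n = 9). Mesenchymal transcripts were abundant too, with VIM (vimentin) at 800.1 ± 40.4, COL1A1 (type I collagen) at 1445 ± 266 and THY1 at 873.9 ± 30.5 CPM, genes singled out after their values were seen. The epithelial adhesion genes EPCAM and CDH1, also singled out afterwards, averaged 4.6 and 9.2 CPM. Of the fixed lists, 24 of 26 mesenchymal transition genes but only 6 of 14 fibroblast genes had enough reads to be tested. COL1A2, the partner chain of COL1A1, and the leukocyte gene PTPRC had no read. CDX2, an intestinal transcription factor, had 1 read in all, and the 2 entries for the intestinal mucin MUC2 had 0 to 5 reads per library. The endothelial, leukocyte and mucin lists had 4, 3 and 4 tested members and were too small to test.

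**Figure D2:**
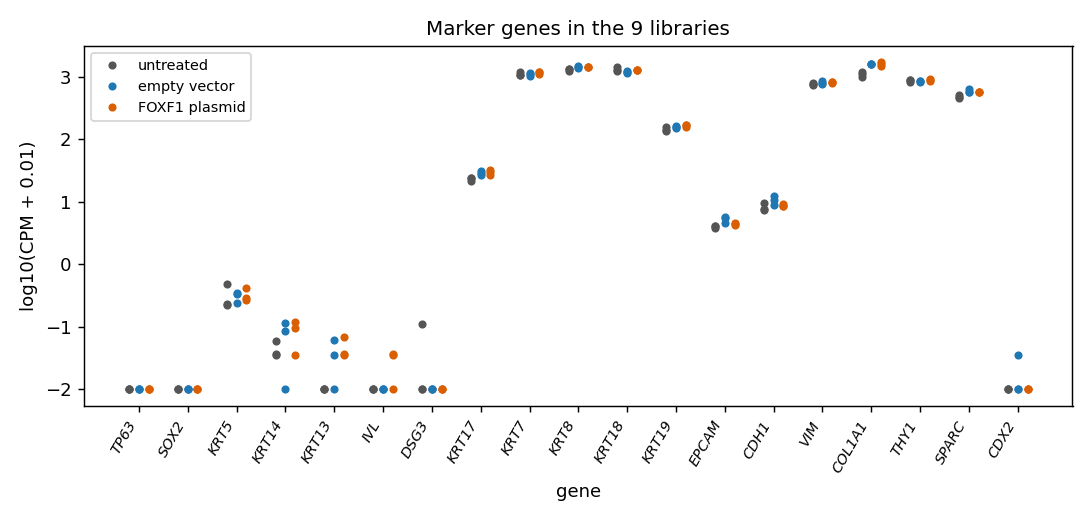
Levels of marker genes in the 9 libraries, as log10 of CPM of the library total plus 0.01, with a point per library coloured by group. TP63 and SOX2 lie at the floor in all 9 libraries, whereas KRT7, KRT8, KRT18 and COL1A1 average 1130, 1396, 1277 and 1445 CPM.

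The comparison of the FOXF1 plasmid with the empty vector asks what FOXF1 adds to transfection. Apart from FOXF1 itself, the transcripts that rose were mitochondrial ones and PRAF2. MT-CYB (cytochrome b) rose from 7567 ± 886 to 11200 ± 1110 CPM (log2 fold change 0.57 ± 0.10, adjusted p = 0.00573). MT-ND4, MT-ND4L and MT-ATP8, subunits of respiratory complexes, rose by 0.54, 0.56 and 0.50 on the log2 scale. The nuclear pseudogenes MTND4P12, MTATP6P1 and MTND2P28 rose by 0.81, 0.58 and 0.55, and since they can share reads with the mitochondrial genome their own level is uncertain. PRAF2, which encodes a membrane protein of the endoplasmic reticulum, rose from 122.9 ± 8.85 to 156.7 ± 10.3 CPM (log2 fold change 0.35 ± 0.07, adjusted p = 0.0391). The mitochondrially encoded share of counts was 11.2% ± 0.76 with the empty vector and 14.1% ± 0.52 with the FOXF1 plasmid (SD, n = 3). In untreated libraries it was 20.9% ± 2.0, so the share with the FOXF1 plasmid was still below that of untreated cells.

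Altogether 9 of 16366 genes were called in this comparison, 9 higher and 0 lower, by the edgeR quasi-likelihood test. At an unadjusted p below 0.05, 833 were higher and 710 lower, DESeq2 called 102 higher and 2 lower, and limma-voom called 13 higher and 0 lower. Without FOXF1 plasmid replicate 2 only FOXF1 was called, without empty vector replicate 2 the count was 2, and without empty vector replicate 1 it was 326, of which 172 were lower. Fold changes moved less than the calls: without FOXF1 plasmid replicate 2 the log2 fold change was 0.49 for MT-CYB, 0.47 for MT-ND4, 0.66 for MTND4P12 (adjusted p = 0.199, 0.199 and 0.052) and 0.29 for PRAF2 (0.815), and without empty vector replicate 2 it was 0.48 for MT-CYB and 0.45 for MT-ND4 (both 0.0984). PRAF2 was not called with scaling by total counts alone (log2 fold change 0.25, adjusted p = 0.274) or with GC and length offsets (0.26, adjusted p = 0.101). Without mitochondrial genes and pseudogenes its log2 fold change was 0.34, and the adjusted p became 0.219 because most other called genes were left out. MT-ATP8 was not called with scaling by total counts alone (0.41, adjusted p = 0.122). Fold changes also followed GC content and transcript length across 16213 genes, with Spearman's rho of 0.387 and -0.272 (genes are not independent replicates).

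Columnar and Barrett-associated genes are the class of epithelial genes that replaces squamous ones in Barrett's metaplasia. Only 15 of the 38 list members had enough reads to be tested. Their median log2 fold change was 0.15, and none of the 15 passed (0 also when adjusted over the list alone). Camera called the list higher (adjusted p = 0.0196), and the call was lost with an estimated correlation (adjusted p = 0.203). KRT18 was at 1284 ± 38.8 against 1106 ± 82.6 CPM (adjusted p = 0.377) and KRT8 at 1437 ± 42.9 against 1318 ± 79.4 CPM (adjusted p = 0.576). SOX9, a columnar progenitor factor, had a log2 fold change of -0.04 ± 0.11 (adjusted p = 0.942). Of the 13 mitochondrially encoded genes, 4 rose (12 when adjusted over the list alone), with a camera adjusted p of 2.55e-36 and an adjusted p = 0.083 with an estimated correlation. Ribosomal protein genes had a median of 0.09, which became -0.01 when libraries were scaled by total counts alone (call lost, adjusted p = 0.0507), and 0 of 27 passed (camera adjusted p = 1.23e-05; adjusted p = 0.871 with an estimated correlation). Cholesterol synthesis genes had a median of -0.08 with 0 of 24 passing (camera adjusted p = 0.047; adjusted p = 0.871 with an estimated correlation). Fry called none of these 4 lists, with an adjusted p of 0.143 for the columnar and the mitochondrial genes. The columnar call was also lost without empty vector replicate 3 (adjusted p = 0.0563) or FOXF1 plasmid replicate 1 (0.0787), the cholesterol call without these libraries (0.257 and 0.72), and the ribosomal call without empty vector replicate 2 (0.0664) or FOXF1 plasmid replicate 3 (0.126). Lists were not rerun with GC and length offsets. Whether the GC and length trends of this comparison contribute to the list calls was therefore not tested.

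The other 18 lists were not called, with camera adjusted p from 0.158 to 0.953, and none of their members passed over all genes. They were squamous basal and differentiation genes, the Hedgehog, Notch, BMP and TGF-beta pathways, Wnt targets, FOXF1 targets described in lung, mesenchymal transition, wound repair, interferon, NF-kappaB, cell cycle, p53, endoplasmic reticulum stress, heat shock, NRF2, immediate early and fibroblast genes. For 7 of the 22 lists the median, the mean and the direction of the test did not all have a single sign, and none of these was called. GLI1, a transcriptional effector of Hedgehog signalling, was at 4.308 ± 0.132 against 3.312 ± 0.510 CPM (log2 fold change 0.38 ± 0.21, adjusted p = 0.603). PTCH1, the Hedgehog receptor, and BMP4 had log2 fold changes of 0.03 ± 0.17 and 0.17 ± 0.22 (adjusted p = 0.971 and 0.865). TGFB1 was at 229.8 ± 18.3 against 190.5 ± 11.4 CPM (adjusted p = 0.169 over all genes) and passed only when adjusted over the list alone (0.0113). Also adjusted over the list alone, 1 member passed as lower in each of the mesenchymal transition and lung FOXF1 target lists (LOX in both; adjusted p = 0.00359 and 0.00164), the cell cycle list (TOP2A; log2 fold change -0.43, adjusted p = 0.0202) and the p53 list (MDM2; 0.0104). In the heat shock list HSPB1 passed as higher (0.21, adjusted p = 0.0324) and HSP90AA1 as lower (-0.34, adjusted p = 0.00856). Among genes outside the called set, the neuropeptide precursor VGF had a log2 fold change of 0.60 (adjusted p = 0.163), and CTB-36O1.7, MTND1P23, RP11-750B16.1 and MT-ND1 had 0.80, 0.75, 0.57 and 0.51 (adjusted p = 0.0808, 0.128, 0.128 and 0.162). At the other end ORC5, MDM2, EDIL3, LOX and MALAT1 had -0.88, -0.71, -0.51, -0.42 and -0.39 (adjusted p = 0.163, 0.162, 0.162, 0.115 and 0.115).

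The empty vector against untreated cells measures the response to transfection itself, and it was far wider. Genes of the unfolded protein and integrated stress responses rose together: PDIA4, a folding enzyme of the endoplasmic reticulum, rose from 137.6 ± 21.8 to 322.6 ± 18.3 CPM (log2 fold change 1.23 ± 0.08, adjusted p = 1.3e-11), HSPA5, its main chaperone, by 0.93, and PSAT1, of serine synthesis, by 0.97. Of the 22 tested members of that list 20 rose and 0 fell (21 and 0 when adjusted over the list alone; camera adjusted p = 3.64e-33; adjusted p = 0.00765 with an estimated correlation). Mitochondrially encoded transcripts fell: MT-CYB from 19490 ± 2420 to 7567 ± 886 CPM (log2 fold change -1.37 ± 0.10, adjusted p = 3.79e-11), and 12 of 13 members in all (12 when adjusted over the list alone; camera adjusted p = 4.14e-63; adjusted p = 0.0107 with an estimated correlation). MT-ND6, the member that did not pass, had -0.21 ± 0.19. The mitochondrial share of counts was 20.9% ± 2.0 in untreated and 11.2% ± 0.76 in empty vector libraries (SD, n = 3).

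The largest rises were of ABCA1 (cholesterol export; log2 fold change 2.30 ± 0.25), INHBE (an activin subunit; 2.03 ± 0.12), NDRG1 (1.83 ± 0.07), ANGPTL4 (1.79 ± 0.18), IGFBP3 (1.52 ± 0.11) and DUSP6 (a phosphatase of ERK; 1.51 ± 0.22), with adjusted p of 1.24e-05 or smaller. NDRG1 went from 120.0 ± 4.91 to 426.9 ± 17.1 CPM. CGRRF1, PFDN4, HSPA13 and CSF2RA rose by 1.48, 1.44, 1.38 and 1.28. The largest falls were of MT-ND4L (-1.41 ± 0.09), BCYRN1 (a noncoding RNA with repeat-derived sequence, so its reads are uncertain; -1.38 ± 0.18), MT-CYB, MT-ND4 (-1.36 ± 0.09), MT-CO2 (-1.31 ± 0.11), LINC01356 (-1.26 ± 0.22), PI3 (the protease inhibitor elafin; -1.22 ± 0.24), MT-ATP8, MT-ND2 and MT-CO3. In all, 1676 genes rose and 1533 fell, 3209 of 16366. When libraries were scaled by total counts alone, the median log2 fold change of all genes moved by 0.246 and 5721 of 6059 calls were higher, 94.4% against 52.2% here. With RLE factors 1472 of 3277 calls were higher (44.9%), and with GC and length offsets 1479 of 3486 (42.4%). The balance of rises and falls thus depends on the scaling. These fold changes followed GC content and transcript length with Spearman's rho of -0.27 and 0.164. Without empty vector replicate 2 the count was 2092.

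Immediate early genes rose, 12 of 22, among them JUN (0.65), MYC (0.47) and DUSP4 (0.66), with a camera adjusted p of 2.32e-06 (adjusted p = 0.145 with an estimated correlation). Wound repair genes rose in 7 of 20 cases, VEGFA by 0.80 and PLAU by 0.40 (camera adjusted p = 0.00709; adjusted p = 0.206 with an estimated correlation). Ribosomal protein genes fell in 15 of 27 cases, among them RPLP2 (-0.63) and RPLP1 (-0.42), and RPL4 rose (camera adjusted p = 1.82e-08; adjusted p = 0.343 with an estimated correlation), and their median of -0.23 became 0.02 with scaling by total counts alone, which moved all genes up by a like amount and kept the camera call (adjusted p = 0.0178). Of 32 cell cycle genes 12 fell, MKI67 (-0.56) and TPX2 (-0.49) among them, and 6 rose (camera adjusted p = 0.0178; adjusted p = 0.144 with an estimated correlation), and with that scaling their median of -0.05 became 0.20 and the call was lost (adjusted p = 0.8). The tested members of the squamous basal list rose in 5 of 13 cases and fell in 1 (camera adjusted p = 0.00822; adjusted p = 0.131 with an estimated correlation); those that rose include LAMB3 (a basement membrane gene; 0.98), and DST fell (-0.75), a call that was lost with scaling by total counts alone (-0.49). Squamous differentiation members rose in 5 of 15 cases and fell in 1, including KLF4 (0.62), EMP1 (0.60) and PPL (0.47), while KRT5 and KRT13 stayed near 0 (camera adjusted p = 0.0214; adjusted p = 0.144 with an estimated correlation). Only 6 of the 14 fibroblast genes were tested, of which 4 rose, with COL6A3 by 0.84 and PDGFRB by 0.47 (camera adjusted p = 0.0153, and adjusted p = 0.322 with an estimated correlation). THY1 had -0.28, which became -0.03, without a call, with scaling by total counts alone. Adjusted over the list alone, the numbers that rose and fell were 12 and 1, 7 and 0, 1 and 16, 7 and 13, 7 and 1, 5 and 1, and 4 and 1 for these 7 lists in the order given. SOX9 rose by 0.58 ± 0.11 (adjusted p = 0.000361), whereas KRT18 and KRT7 had -0.41 and -0.26 (adjusted p = 0.000191 and 0.012), which became -0.16 and -0.01 (0.0294 and 0.924) with scaling by total counts alone. Fry kept all 9 calls and added the BMP and TGF-beta (adjusted p = 0.00268), FOXF1 lung target (0.00506), p53 (0.0103) and NF-kappaB lists (0.0171) as higher. Without empty vector replicate 1 the calls of the squamous differentiation, fibroblast and cell cycle lists were lost (adjusted p = 0.103, 0.103 and 0.129). The other 13 lists were not called by camera, with adjusted p from 0.0873 to 0.911, and 64 of their members passed over all genes.

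The FOXF1 plasmid against untreated cells combines transfection and FOXF1. The leading genes after FOXF1 were those of the empty vector response: ABCA1 (log2 fold change 1.91 ± 0.25), INHBE (1.87 ± 0.12), ANGPTL4 (1.85 ± 0.18) and NDRG1 (1.69 ± 0.07) rose, each with an adjusted p of 6.02e-06 or smaller. The largest falls were of RGS2 (a regulator of G-protein signalling; -1.07 ± 0.23), DST (-1.05 ± 0.20), PHIP (-1.01 ± 0.26), NIPBL (cohesin loading; -0.93 ± 0.18) and MT-CO2 (-0.93 ± 0.11). In all 757 genes rose and 637 fell, 1394 of 16366. When libraries were scaled by total counts alone, the median log2 fold change of all genes moved by 0.148 and 2320 of 2500 calls were higher (92.8% against 54.3% here), and with GC and length offsets 976 of 2217 (44.0%). Without untreated replicate 1 or 2 or FOXF1 plasmid replicate 2 or 3 the count was 883, 817, 927 or 875.

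In this comparison 19 of 22 endoplasmic reticulum stress genes rose (19 when adjusted over the list alone; camera adjusted p = 8.68e-44; adjusted p = 0.00386 with an estimated correlation) and 11 of 13 mitochondrially encoded genes fell (12 when adjusted over the list alone; camera adjusted p = 8.24e-40; adjusted p = 0.0353 with an estimated correlation). Another 10 lists were called by camera and lost with an estimated correlation. Higher were immediate early (adjusted p = 0.0767 with an estimated correlation), squamous differentiation (0.0551), squamous basal (0.0776), fibroblast (0.109), wound repair (0.118), BMP and TGF-beta (0.118) and mesenchymal transition genes (0.403), and lower were cell cycle (0.0776), ribosomal protein (0.435) and cholesterol synthesis genes (0.31). The medians of these lower lists, -0.09, -0.13 and -0.09, became 0.06, 0.02 and 0.05 with scaling by total counts alone, which moved all genes up by a like amount, and the calls were lost (adjusted p = 0.327, 0.135 and 0.47). The numbers that rose and fell in these 10 lists, in the order given, were 9 and 0, 6 and 0, 2 and 1, 4 and 0, 5 and 0, 3 and 1, 4 and 1, 1 and 6, 0 and 6, and 0 and 3. Adjusted over the list alone they were 13 and 0, 7 and 0, 6 and 1, 4 and 0, 6 and 0, 5 and 1, 5 and 1, 3 and 8, 0 and 11, and 0 and 5. The BMP and TGF-beta call was also lost without untreated replicate 2 or 3 or FOXF1 plasmid replicate 1 or 2 (adjusted p = 0.0523, 0.0796, 0.0575 and 0.115) and with scaling by total counts alone (0.0674), the mesenchymal call without untreated replicate 2 or 3 or FOXF1 plasmid replicate 2 (0.0905, 0.0737 and 0.3), and the cholesterol call without untreated replicate 3 or FOXF1 plasmid replicate 1 (0.156 and 0.148). Fry did not call the mesenchymal (adjusted p = 0.0778), cholesterol (0.101) and ribosomal lists (0.169), and added the columnar (0.0219), p53 (0.0294) and FOXF1 lung target lists (0.0135) as higher. The other 10 lists were not called by camera, with adjusted p from 0.091 to 0.921. MKI67 fell by 0.62 and CENPF by 0.93 on the log2 scale. SOX9 and CLDN7 (a columnar tight junction gene) rose by 0.54 and 0.53 (adjusted p = 0.00217 and 0.00598), and KRT7, KRT8 and KRT18 had -0.09, 0.00 and -0.20 (adjusted p = 0.5, 0.997 and 0.108).

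**Figure D3:**
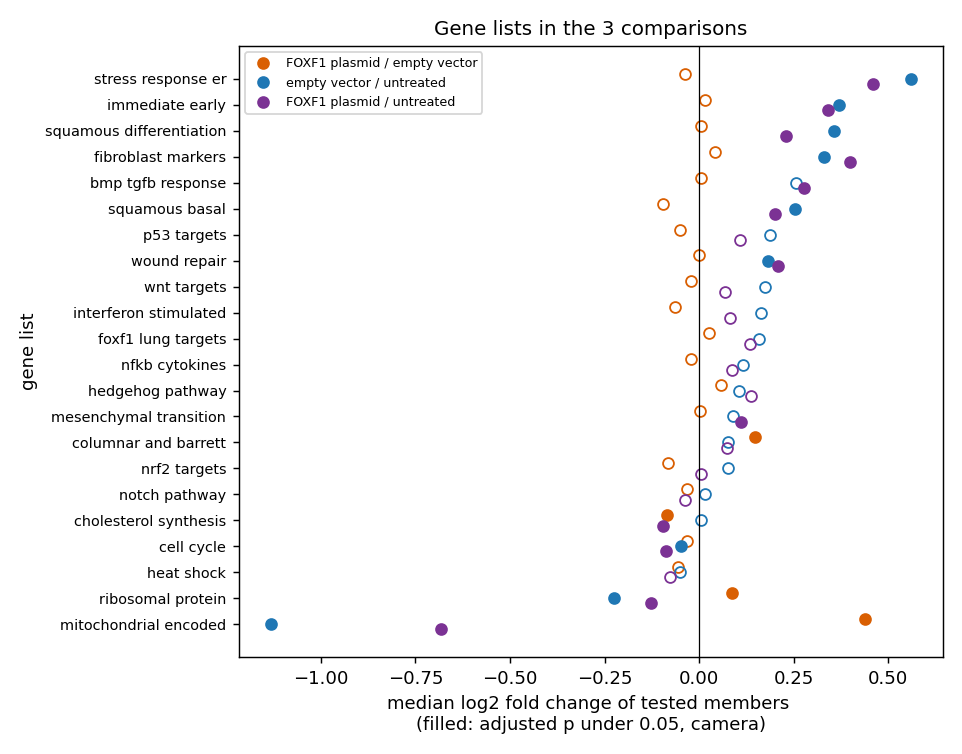
Median log2 fold change of the tested members of 22 gene lists in the 3 comparisons, filled where camera with the preset correlation gave an adjusted p below 0.05. Stress response genes lie at 0.56 and mitochondrially encoded genes at -1.13 for the empty vector against untreated cells, and the medians of ribosomal protein genes change sign in all 3 comparisons when libraries are scaled by total counts alone, which moves the median of all genes by -0.098, 0.246 and 0.148 for FOXF1 plasmid against empty vector, empty vector against untreated and FOXF1 plasmid against untreated.

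The responses of the transfected groups, each against the untreated libraries, overlapped. There were 1232 genes called in both, 672 higher and 560 lower in both and 0 in opposite directions, where independent lists of these lengths would share 77.5 and 59.7. The fold changes had Pearson's r of 0.722 across genes, against a mean of 0.510 and a range of 0.480 to 0.535 in the simulated sets without effects. Their covariance was 0.117, against 0.0379 in the simulated sets, a difference of 0.0787. Those sets draw genes independently, so their range is no bound for genes that vary together. Part of the excess in overlap may come from the shared untreated libraries. Of the 3209 genes called for the empty vector, 3193 had the same sign for the FOXF1 plasmid and 2927 a smaller fold change there; this number is raised by choosing genes on the empty vector libraries.

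**Figure D4:**
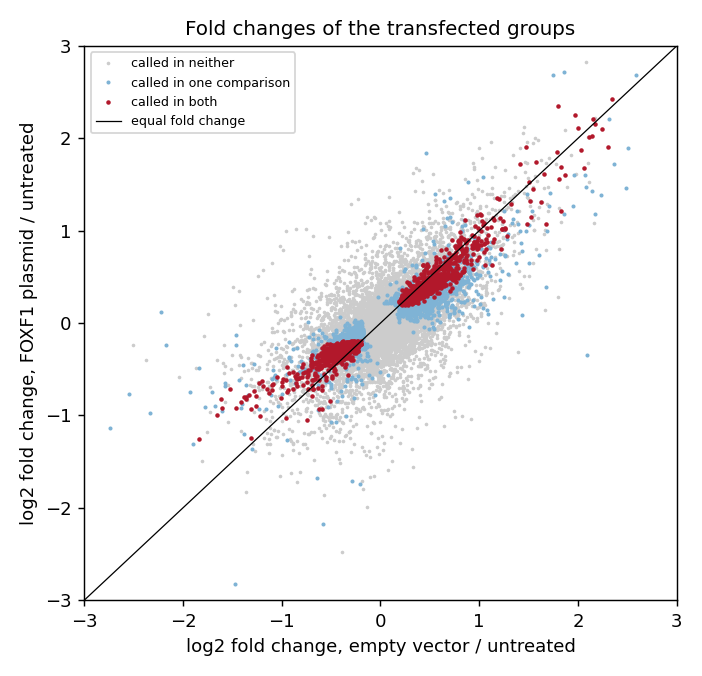
Log2 fold changes against untreated cells for the empty vector (x axis) and the FOXF1 plasmid (y axis), with a point per tested gene, red where called in both comparisons, and a line of equal fold change; 3 genes lie outside the axes. The 1232 genes called in both comparisons have the same sign in both.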

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

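The alternatives without mitochondrial genes and with GC and length offsets were chosen after the data were seen; the cause of a change was not tested unless stated. For the FOXF1 plasmid against the empty vector, the 9 calls became 16 with RLE factors, 96 without a filter on low counts, 104 with DESeq2 (7 of the 9 among them), 2 at a fold threshold of 1.2, 1 without mitochondrial genes and pseudogenes, which removes 7 of the 9 by construction, and 1 to 326 when a library was left out. DESeq2 gave an adjusted p to 3110 of 28753 genes here and none to MTND4P12 or to FOXF1 (FOXF1: log2 fold change 7.05, unadjusted p = 1.42e-06), so DESeq2 has no entry for them. The 4 called lists became 0 with an estimated correlation, 0 with fry, and 2 to 5 when a library was left out. FOXF1 kept its call in all other settings, from 6.34 to 10.85 with a library left out, the highest without empty vector replicate 3, the only empty vector library with FOXF1 reads. Each of the other 8 calls was lost without FOXF1 plasmid replicate 2, with log2 fold changes still of 0.29 for PRAF2, 0.44 for MT-ATP8 and MTND2P28, and up to 0.66 for MTND4P12.

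For the empty vector against untreated cells, the 3209 calls became 6059 with total counts alone, 689 at a fold threshold of 1.2, and 2092 to 3897 with a library left out. The 9 lists became 2 with an estimated correlation, 13 with fry and 6 to 11 with a library left out. For the FOXF1 plasmid against untreated cells, the 1394 calls became 2500 with total counts alone, 2217 with GC and length offsets, 195 at a fold threshold of 1.2, and 817 to 1531 with a library left out. The 12 lists became 2 with an estimated correlation, 12 with fry (3 lost and 3 others gained) and 9 to 15 with a library left out. The correlation of the responses of the transfected groups became 0.899 for genes with a mean log2 CPM of at least 3, which leaves fewer noisy genes, and 0.636 to 0.777 with a library left out. No simulated value without effects was computed for the abundant genes, so 0.899 has no such reference. CCND1, lower after the empty vector, had 0.01 with total counts alone.

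Of the named genes called for the empty vector, 50 of 91 kept their call in every setting, and of those for the FOXF1 plasmid against untreated cells 29 of 70; a fold threshold of 1.2 took 40 and 41 of these calls. With a replicate block the counts of calls were 16, 3292 and 1544 in the order of comparisons above, and the counts of called lists stayed at 4, 9 and 12. Libraries with equal replicate numbers showed no sign of pairing: correlations of their deviations ran from -0.09 to 0.084, and 3 of 9 pairs were best with their own number. With so few libraries, and with GC trends that differ between them, a pairing is not excluded. Depth limits genes of low level, which the simulated changes, all at a mean log2 CPM above 1, did not cover. Of the smallest simulated changes 42.9% were recovered for the FOXF1 plasmid against the empty vector and 31.4% in each comparison with untreated cells. Each share comes from 1 random draw of 70 genes, so their difference is not a difference between comparisons.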

Other observations

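The tests of held-out libraries for chance, of a uniformly smaller response and of an equal fall in nuclear respiratory genes were chosen after the related values had been seen, as were the gene lists of the first paragraph. Targets of the hypoxia-inducible factors (HIF) rose after transfection: of 24 targets that were not among the leading genes, 19 rose and 0 fell with the empty vector and 15 rose with the FOXF1 plasmid. ADM, PDK1 and P4HA1 rose by 1.21, 1.15 and 1.07 on the log2 scale with the empty vector. The list was called higher (median 0.61, camera adjusted p = 4.21e-24; adjusted p = 0.000676 with an estimated correlation), so a HIF response of transfected cells is a hypothesis that these data are consistent with; its trigger was not tested. Genes of amino acid supply under the factor ATF4 rose in 25 of 28 cases with the empty vector and fell in 1 (median 0.51, camera adjusted p = 3.94e-31; adjusted p = 0.000676 with an estimated correlation), STC2 by 1.15 and MTHFD2 by 0.84; several members are also in the endoplasmic reticulum stress list or were seen beforehand, so this is not independent of it. Glycolysis genes rose in 6 of 16 cases and fell in 2 (median 0.17; camera adjusted p = 3.47e-05; adjusted p = 0.0773 with an estimated correlation). With the FOXF1 plasmid against untreated cells 6 rose and 0 fell (median 0.16; camera adjusted p = 1.23e-09; adjusted p = 0.0185 with an estimated correlation). HK2, SLC2A1 and PGK1, which rose in both comparisons, are also in the HIF list. Genes of mitochondrial translation and expression fell in 6 of 26 cases and rose in 2 (median -0.08; camera adjusted p = 0.0443; adjusted p = 0.082 with an estimated correlation), and with the FOXF1 plasmid against untreated cells 2 fell and 1 rose without a call (median -0.03, adjusted p = 0.0568). With the FOXF1 plasmid against the empty vector, none of the members of these lists passed; camera called the HIF list lower (median -0.11, adjusted p = 0.0032; adjusted p = 0.173 with an estimated correlation).

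Of 56 squamous markers 33, TP63 and KRT5 among them, were near 0 in all 9 libraries, although the cells are labelled as esophageal squamous; others were expressed, such as PPL, EVPL, ITGB4, KRT17 and PAX9 (114.3, 92.1, 75.1, 27.4 and 16.9 CPM). An explanation by reads lost to overlapping genes in counting is argued against: 0 of the 33 near-absent markers have at least 50% of their exon length inside exons of another gene. A culture other than squamous keratinocytes, or EPC2 cells that keep only part of their squamous program, may both be open; the expressed members do not decide between them, and neither was tested, because no reference profile of EPC2 was used here. Gene changes in these libraries are therefore those of cells with high KRT8, KRT18, VIM and COL1A1 and without TP63 reads.

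On average over genes of the transfection response, the FOXF1 plasmid libraries lay between the untreated and the empty vector libraries, though not on every axis: on the first principal component empty vector replicate 1 (7.9) lay nearer the untreated libraries (-42.4 to -19.3) than FOXF1 plasmid replicates 1 and 3 (11.4 and 12.5). An axis was set to 0 at a held-out untreated and 1 at a held-out empty vector library, with 500 genes chosen on the remaining libraries. The median position of the FOXF1 plasmid libraries on it was 0.74 (0.63 to 0.88 over 9 hold-outs). Choosing genes on the scored libraries therefore does not account for the position alone. The hold-outs reuse the same 3 libraries of each group, so chance differences between libraries are not excluded. The median was 0.75 without mitochondrial genes and 0.78 after removal of each library's GC and length trend, so neither accounts for the position alone. The covariance of the fold changes of FOXF1 plasmid against empty vector with those of empty vector against untreated was -0.0586, below the -0.0391 to -0.0332 of simulated sets, but those sets draw genes independently and so exclude nothing. The mitochondrial list stood at 0.63 of its empty vector change (0.58 to 0.67 with a library left out). The stress list stood at 0.89 (0.84 to 0.93) and the ribosomal list at 0.58 (0.39 to 0.8). Immediate early genes stood at 1.04 (0.86 to 1.19) and cell cycle genes at 1.45 (0.99 to 2.8), so not every list lay between. The cell cycle ratio divides by a small mean change of -0.066. Ranges over single left-out libraries do not measure the sampling error of a ratio, so a response smaller by a uniform factor is not excluded. A weaker exposure to transfection, acting equally or unequally on genes, and an effect of FOXF1 may both explain the position, and the design does not separate them.

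Mitochondrially encoded transcripts fell after the empty vector, with a median log2 fold change of -1.13. GC content bias is argued against: the 78 abundant nuclear genes within the same GC range (39.6% to 47.7%) had a median of -0.035. Nuclear-encoded respiratory genes had a median of -0.14, with 13 of 31 lower and 3 higher (camera adjusted p = 0.00049; adjusted p = 0.238 with an estimated correlation), so whether they took part to a small extent stays open. A fall of the same size is argued against, since the lowest of the 31 members had -0.64. A biological effect of transfection may remain, untested.

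With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For the FOXF1 plasmid against the empty vector, 2 of 10 splits called as many genes, the real split with 9 included; the highest other called 44. That split sets empty vector replicate 1 with FOXF1 plasmid replicates 2 and 3, and points to a structure of the samples. Deviations from the mean of all libraries followed GC content with Spearman's rho of 0.277 in empty vector replicate 1, -0.395 and -0.598 in empty vector replicates 2 and 3, and -0.016, 0.446 and -0.037 in FOXF1 plasmid replicates 1, 2 and 3. For the empty vector against untreated cells (3209 genes) and the FOXF1 plasmid against untreated cells (1394 genes), 1 of 10 splits called as many, the real split itself, and the highest other called 0.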
